A study of Homo sapiens with 12 samples.

How the data were processed

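Total RNA was measured on single-colour expression arrays from human erythroid progenitors grown from CD34-positive blood precursor cells. The cells had received either control siRNAs with no intended target or siRNAs against BCL11A on day 0 of erythroid differentiation and were harvested on day 7, with 6 arrays in each group. Per the labels' protocols, RNA was copied into cDNA from an oligo-dT primer carrying a T7 promoter, transcribed in vitro with biotinylated nucleotides, purified, and stained with a streptavidin-phycoerythrin conjugate. Samples were placed in their group by their source names, and the array number (1 to 6 in each group) was read from the titles.

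The deposited values are linear intensities, 1 per probe set and array, and not log values, since they run from 0.57 to 16566 with none below 0. The background correction, the summary of probes into probe sets and the scaling between arrays are not given in the sources used here. The scale was judged from the values alone: array median intensities lay between 21.8 and 24.3, so the arrays had been brought to nearly the same level before deposit. Of 656100 values, 17389 (2.65%) were exactly 1 and 60 were below 1. Intensity is a relative level, and levels of different probe sets were compared only to pick the brightest probe set of a gene and to set aside dim ones. No sequencing depth exists for arrays, and the number of arrays limits the precision.

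Probe sets were named from the platform annotation: 41097 of 54675 list 1 gene symbol, 1801 list several and 11777 list none. A probe set with several symbols was given no gene name of its own, except that the γ-globin and α-globin probe sets are reported as probe sets that list HBG1 with HBG2, or HBA1 with HBA2, and cannot separate them. No symbol was changed by a match of gene identifiers to the reference table, and 54 probe sets with 1 symbol had no match there. RNA quality was compared on the control probe sets of GAPDH and ACTB, and other control probe sets are not reported here. The 62 control probe sets and 95 probe sets of sex-linked genes were left out, which left 54518 probe sets and 19740 genes.

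Values under 1 were raised to 1 and log2 was taken. The medians of the 12 arrays spanned 0.16 on the log2 scale, under the 0.25 above which quantile normalization would have been added, so the deposited scaling was kept. Each gene was represented by its brightest probe set (highest mean log2 value over all 12 arrays). Differences (BCL11A siRNA minus control siRNA) were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and p was adjusted by the Benjamini-Hochberg method over all genes, or over all probe sets for the values given by probe set. An adjusted p under 0.05 counted as past the test. Intervals are 95% intervals from the same fit. For the BCL11A and globin probe sets a two-sided exact permutation test over all 924 splits of the 12 log2 values into 6 and 6 was run as well, adjusted over the 4 BCL11A probe sets or the 20 globin probe sets.

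A total of 24 gene lists was fixed. Those with at least 5 measured members (22 lists) were tested two-sided with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 22 lists. Fry asks whether the genes of a list move, on balance, to 1 side and makes no comparison with other genes. Members past the test were counted after adjustment over all genes and after adjustment over the list alone. A gene can belong to more than 1 list.

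Samples, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. That rule named BCL11A, the globin genes, up to 12 genes with the largest increase and up to 12 with the largest decrease among genes past the test whose higher group lay above the median over all genes (log2 5.49), and up to 4 members of each list with the smallest p. Genes named outside the rule are said to have been chosen after their values were seen. The labels name no batch. Arrays numbered 1 to 3 and arrays numbered 4 to 6 turned out to differ in both groups, so these sets were added, after the data had been seen, as a block in the same fits, and the gene, probe set and gene list comparisons were repeated within each set. The sets are balanced over the groups, with 3 arrays of each group in each set. Nothing in the labels says that the arrays came from separate cultures or donors, so the p-values measure only the spread between these samples, which may be technical.

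The alternatives were quantile normalization, median centring, low values raised to the 20th percentile, removal of the dimmer probe sets, the mean over all probe sets of a gene, removal of probe sets ending in _x_at or _s_at, no intensity trend, a robust variance model, array weights, the array number as a block, each array left out in turn, and stricter thresholds (adjusted p under 0.01, or a difference of at least 1.5-fold). The fits were tested on simulated data for 19740 genes in 6 against 6 arrays: 25.4% of genes shifted by 0.3 on the log2 scale were recovered, 80.6% of those shifted by 0.6 and 97% of those shifted by 1. In that simulation 5 of 140 calls were false, and no gene was called when none was shifted. The simulated noise was independent between genes and held no array sets, and only genes above the median level were shifted. These rates are therefore not error rates for the real arrays. Files were read with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.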

Results

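The series compared human erythroid progenitors, derived from CD34-positive cells, that had received control siRNAs or siRNAs against BCL11A. BCL11A is a zinc-finger repressor of the fetal γ-globin genes, and the comparison asks which transcripts differ after 7 days of erythroid differentiation when it is targeted. There were 6 arrays per group, numbered 1 to 6. No pair of arrays held identical values, and Spearman correlations between pairs over all probe sets ran from 0.925 to 0.954. The 3′ minus 5′ log2 difference of control transcripts, a sign of RNA quality, was 0.46 ± 0.12 and 0.44 ± 0.11 for GAPDH (SD, n = 6, exact permutation p = 0.736) and 0.83 ± 0.18 and 0.68 ± 0.13 for ACTB (n = 6, exact permutation p = 0.126). Within arrays 4 to 6 ACTB ran from 0.70 to 1.16 on the control arrays and from 0.53 to 0.64 on the BCL11A siRNA arrays, without overlap, though 3 arrays against 3 cannot give an exact p under 0.1. GAPDH overlapped within both sets, as did ACTB within arrays 1 to 3.

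Red cell genes differed between arrays 1 to 3 and arrays 4 to 6 in both groups. SLC4A1, the anion exchanger of the red cell membrane, read 1330 to 1377 on control arrays 1 to 3 and 2625 to 2856 on control arrays 4 to 6, and 1071 to 1184 against 1799 to 1851 on the BCL11A siRNA arrays (log2 difference between the sets 0.88, limma adjusted p = 7.83e-07). HBM, an α-like globin, ALAS2, the first enzyme of erythroid heme synthesis, and TXNIP, an inhibitor of thioredoxin, were also higher in arrays 4 to 6, by 0.53, 0.41 and 0.59 on the log2 scale. GATA2, a transcription factor of early progenitors, and TPSB2, a mast cell tryptase, were lower there (-0.46 and -0.63). Not all related genes differed in this way. The α-globin, HBB and γ-globin probe sets differed by -0.11 to 0.03 between the sets, none past the limma test. APOC1, of the early erythroid progenitor list, was higher in arrays 4 to 6 (0.60), and that list did not pass (median -0.04, camera adjusted p = 0.185). These genes were chosen after their values were seen. With group in the limma model, 377 genes differed between the sets, 213 higher and 164 lower in arrays 4 to 6. The labels do not say what the sets are, so values with the sets as a block and within each set stand beside the results.

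**Figure D1:**
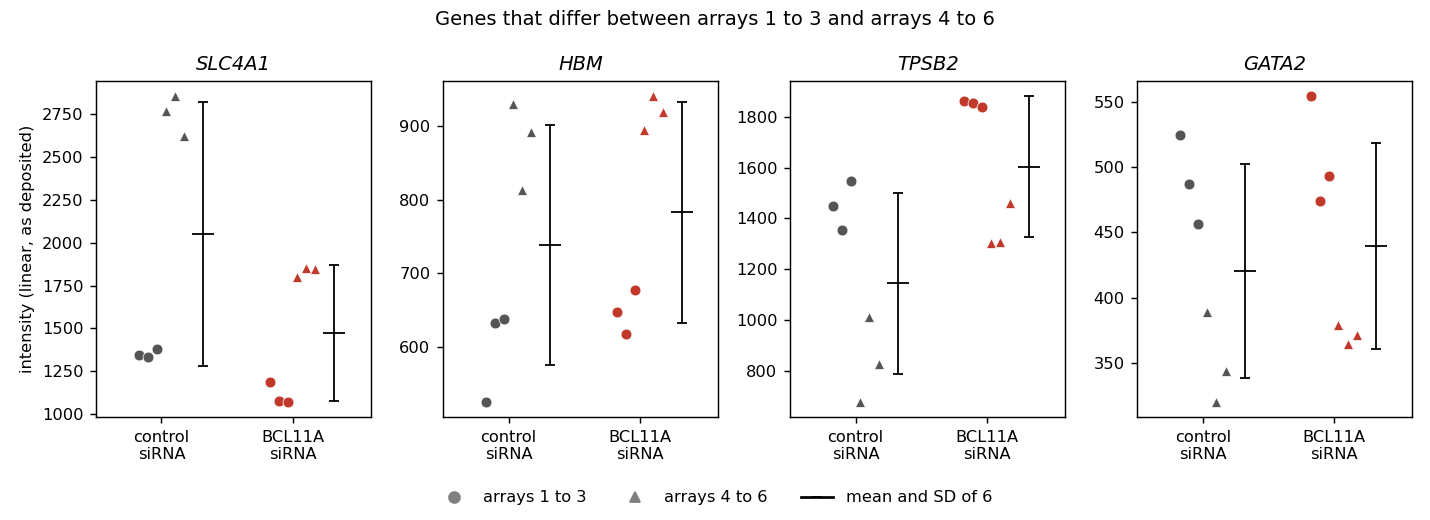
Deposited linear intensity (y axis of each panel) of SLC4A1, HBM, TPSB2 and GATA2 on each array of the control siRNA and BCL11A siRNA groups; circles are arrays 1 to 3, triangles arrays 4 to 6, and black marks the mean and SD of 6 arrays. In both groups SLC4A1 and HBM are higher, and TPSB2 and GATA2 lower, on arrays 4 to 6.

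The targeted transcript itself showed no difference past the tests. The brightest of 4 BCL11A probe sets, 219497_s_at, read 430 ± 65.3 on the control arrays and 371 ± 38.4 on the BCL11A siRNA arrays (SD, n = 6), a difference of -13.3% (log2 -0.21, SE 0.09, 95% interval -0.39 to -0.02). Individual values ran from 384 to 560 in the control group and from 331 to 437 in the BCL11A siRNA group, so the groups overlapped. Control array 4 had the highest value, and without it the difference was -0.13 (adjusted p = 0.697). The difference did not pass the limma test over all probe sets (adjusted p = 0.5, or 0.397 with the array sets as a block), nor the exact permutation test (p = 0.0541, 0.216 adjusted over the 4 probe sets). It was -0.24 within arrays 1 to 3, where the groups did not overlap, and -0.17 within arrays 4 to 6. The other probe sets gave -0.09 (222891_s_at), -0.03 (219498_s_at) and -0.03 (210347_s_at), with adjusted p of 0.789, 0.935 and 0.938. The last pair turned positive with median centring, and 210347_s_at also with quantile normalization. The annotation does not say which transcripts of BCL11A each probe set reads.

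The γ-globin probe sets, by contrast, separated the groups completely. Probe set 213515_x_at, which lists HBG1 and HBG2, read 10720 ± 206 on the control arrays and 12110 ± 483 on the BCL11A siRNA arrays (SD, n = 6), 12.9% higher (log2 0.18, SE 0.04, 95% interval 0.08 to 0.27). Probe sets 204419_x_at and 204848_x_at, for the same pair of genes, were 12.6% and 11.9% higher. Bright globin probe sets can be close to saturation, and 213515_x_at read up to 12654, where the highest value in the data is 16566. Whether this altered the size of the differences was not tested. All 6 BCL11A siRNA arrays exceeded all 6 control arrays on each of the 3 probe sets, which gave an exact permutation p of 0.00216, the smallest that 924 splits allow, and 0.0144 adjusted over the 20 globin probe sets. The adjustment counts each of the 3, although they list the same pair of genes on the same arrays and are not independent. The limma test over all probe sets was not passed (adjusted p = 0.183, 0.19 and 0.21, and 0.0581, 0.0729 and 0.0835 with the array sets as a block). The differences were 0.12, 0.14 and 0.13 within arrays 1 to 3 and 0.23, 0.21 and 0.20 within arrays 4 to 6.

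The other globins showed smaller or more variable differences. HBD, the δ-globin of adult hemoglobin, read 9687 ± 880 on the control arrays and 8672 ± 628 on the BCL11A siRNA arrays (SD, n = 6, -10.4%, log2 -0.16), with exact permutation p = 0.0498, 0.249 after adjustment, and limma adjusted p = 0.475, or 0.0723 with the array sets as a block. Its difference was -0.13 within arrays 1 to 3 and -0.19 within arrays 4 to 6. For HBB, the adult β-globin, the bright probe sets differed by 0.03 to 0.05 and for α-globin (HBA1 with HBA2) by 0.02 to 0.05, with limma adjusted p of at least 0.808. All of these bright probe sets were negative within arrays 1 to 3 (-0.13 to -0.04) and positive within arrays 4 to 6 (0.11 to 0.22). Their intensities reached 16566, the top of the values in the data. The fourth HBB probe set gave -0.003 and changed sign with both scalings. HBBP1, the pseudogene of the β-like cluster, differed by 0.06, HBM by 0.09, and the embryonic globin HBZ by 0.39. For HBE1, another embryonic globin, 205919_at gave 0.10 and the dim 217683_at gave -0.35 (-0.87 within arrays 1 to 3 and 0.17 within arrays 4 to 6). The value for HBQ1 was -0.03 and turned positive with median centring. None of these passed either test, and HBZ was dim (25.3 ± 10.4 and 30.9 ± 5.1, SD, n = 6). Of the measured members of the globin lists, 4 β-like and 3 α-like, 0 passed the test over all genes or adjusted over the list alone. HBG1, HBG2, HBA1 and HBA2 share their probe sets and are not among these members.

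**Figure D2:**
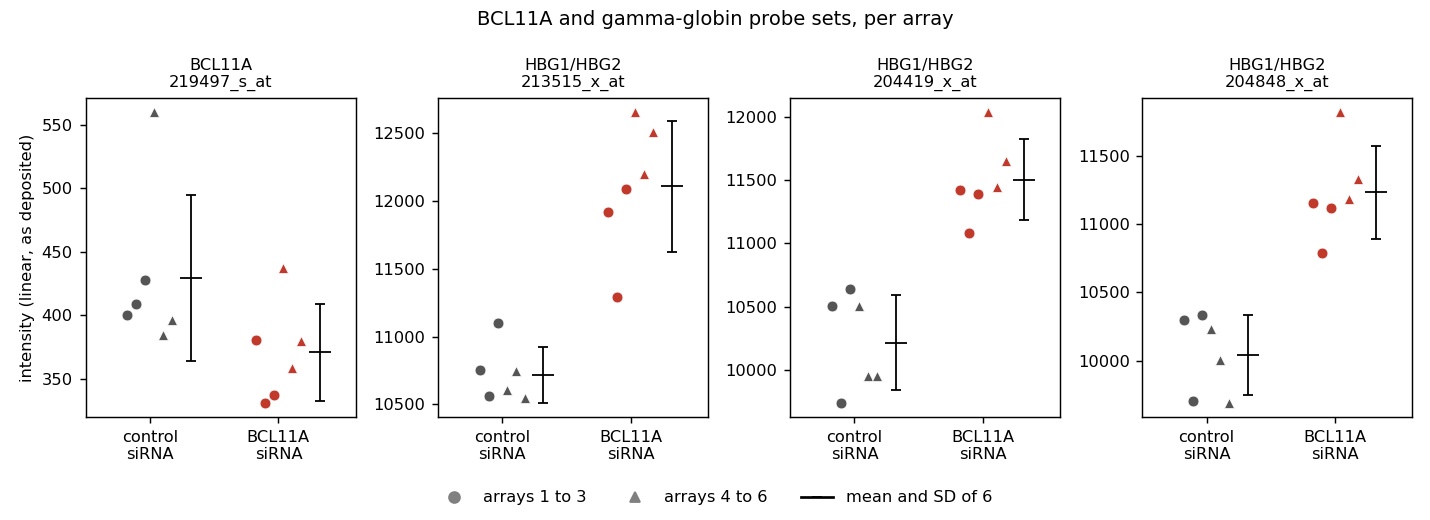
Deposited linear intensity (y axis of each panel, not starting at 0) of the brightest BCL11A probe set and the 3 γ-globin probe sets on each array of the control siRNA and BCL11A siRNA groups; circles are arrays 1 to 3, triangles arrays 4 to 6, and black marks the mean and SD of 6 arrays. BCL11A overlaps between the groups, whereas on 213515_x_at control arrays lie between 10551 and 11100 and BCL11A siRNA arrays between 11294 and 12654.

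Across all genes, BCL11A siRNA arrays differed from control arrays in a small set of genes that mostly fell. Of 19740 genes tested, 36 passed, 5 higher and 31 lower in the BCL11A siRNA group. Over all genes, 227 (1.15%) separated the 6 arrays of one group from the 6 of the other, where chance gives 0.216%, and all 36 were among them. At an unadjusted p under 0.05 there were 2111 genes (696 higher and 1415 lower), where chance would give 987. Probe sets taken singly gave 31 calls, 6 higher and 25 lower. A fit with the array sets as a block gave 203 genes (28 higher, 175 lower), including all 36. Within arrays 1 to 3 alone 9 genes passed, and within arrays 4 to 6 alone 119 (57 higher, 62 lower).

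The 5 genes that rose encode enzymes and regulators. HBG1, HBG2, HBA1 and HBA2 have no probe set of their own, so they were not among the genes tested and could not be called. PTGES, a prostaglandin E synthase, rose 1.6-fold on 1 probe set (log2 0.68, SE 0.07, adjusted p = 0.00033). Its second probe set gave 0.28 (limma adjusted p over all probe sets 0.415). WNK3, a kinase that controls chloride cotransporters, rose 1.72-fold (0.78, SE 0.08, adjusted p = 0.00033). ANPEP, a surface aminopeptidase of myeloid and epithelial cells, rose 1.57-fold (0.65, SE 0.10, adjusted p = 0.00818). GATA5, a transcription factor of heart and endoderm development, went from intensities of 8.1 to 32.4 in the control group to 46 to 76.2 (1.64, SE 0.28, adjusted p = 0.0203), a low level on both sides. ENOX2, a cell-surface NADH oxidase, rose 1.49-fold on 1 probe set (0.58, SE 0.10, adjusted p = 0.0312), while its other probe sets gave 0.13, 0.01 and -0.10. When 1 array at a time was left out, GATA5 lost its call in 5 of 12 fits (without control array 4 or BCL11A siRNA array 1, 3, 4 or 6, adjusted p up to 0.0628). ENOX2 lost its call in 7 of 12 (without control array 3 or 5 or BCL11A siRNA array 2, 3, 4, 5 or 6, up to 0.0959).

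Among genes bright enough for the naming rule, those that fell most include an adult red cell enzyme, several metabolic enzymes and a calcium-binding protein. CALB1, the calcium-binding protein calbindin, fell by 64% (log2 -1.47, SE 0.27, adjusted p = 0.0312). SCRN1, a protein of regulated secretion, fell by 58% (-1.25, SE 0.16, adjusted p = 0.0028). SLC2A3, a glucose transporter, fell by 54.2% (-1.13, SE 0.16, adjusted p = 0.00639), and IMPA2, an inositol monophosphatase, fell by 52.2% (-1.06, SE 0.16, adjusted p = 0.00818). CA1, a red cell carbonic anhydrase whose level rises after birth, went from 711 to 1078 on the control arrays to 417 to 516 on the BCL11A siRNA arrays (-0.95, SE 0.10, adjusted p = 0.000595). AK4, a mitochondrial adenylate kinase, and C11orf96, an open reading frame of unassigned function, had -0.86 each, near the threshold (adjusted p = 0.0499 each). SERPINE2, an inhibitor of serine proteases, had -0.78, ENO2, a glycolytic enolase, -0.72, ACSBG1, an acyl-CoA synthetase, -0.57, PKM, the pyruvate kinase of most tissues, -0.57 and CYSTM1, a small membrane protein, -0.56 (adjusted p from 0.00087 to 0.0109). Dim second probe sets gave -0.03 for CA1, -0.23 for C11orf96, -0.34 for SERPINE2, -0.29 for ACSBG1 and -0.32 for PKM. The further probe sets of CALB1, SLC2A3 and AK4 ran from -1.19 to -0.49. When 1 array at a time was left out, CALB1 lost its call in 8 of 12 fits (adjusted p up to 0.0959) and kept it only without control array 1, 2 or 3 or BCL11A siRNA array 6. AK4 and C11orf96 lost theirs in 10 of 12 (up to 0.138 and 0.143) and kept them only without control array 2 or BCL11A siRNA array 5.

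Of these named genes, CALB1, SLC2A3, CA1 and AK4 also differed between the array sets, being higher in arrays 4 to 6 by 0.97, 0.57, 0.33 and 0.61. Within arrays 1 to 3 and within arrays 4 to 6 the BCL11A siRNA differences were -1.30 and -1.65 for CALB1, -1.06 and -1.19 for SLC2A3, -0.78 and -1.12 for CA1, and -0.92 and -0.80 for AK4. With the array sets as a block their adjusted p were 4.74e-06, 1.19e-06, 1.19e-06 and 8.4e-06. The interaction of group and set was not past the limma test for any of the 36 genes (adjusted p of at least 0.132, for CXCL8, with -1.06 within arrays 1 to 3 and -2.73 within arrays 4 to 6). The remaining 19 genes past the test were all lower. The largest log2 differences of all were among them, at a low level. These were TIMP4, an inhibitor of metalloproteinases (log2 -2.75, from a mean log2 intensity of 3.17 to 0.42), CXCL8, described with the inflammatory genes (-1.89), and LOC100505711, a locus of unassigned function (-1.88, from 4.07 to 2.20). The BCL11A siRNA means of TIMP4 and LOC100505711 lay below the 20th percentile of all values (log2 2.625), so the size and rank of their falls are uncertain. Brighter genes of the 19 included ITGA2B, the platelet integrin αIIb (-0.54), P4HA1, a collagen prolyl hydroxylase (-0.50), the transcription factor gene JUND (-0.42) and the homeobox gene HOXB2 (-0.38). All but ITGA2B and CXCL8 were named here after their values were seen.

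**Figure D3:**
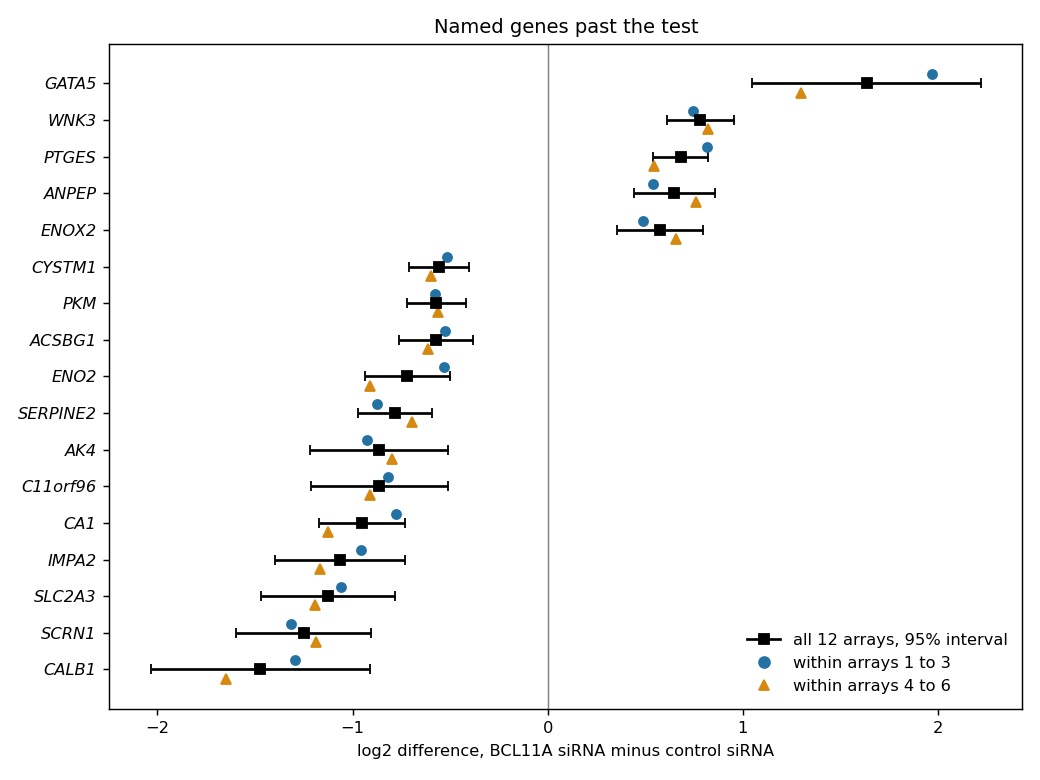
Log2 difference (x axis, BCL11A siRNA minus control siRNA) of the 17 named genes past the test; squares with 95% intervals are all 12 arrays, circles the difference within arrays 1 to 3 and triangles that within arrays 4 to 6. CALB1 has the lowest value over all 12 arrays (-1.47) and within arrays 4 to 6 (-1.65). Within arrays 1 to 3 SCRN1 (-1.31) lies just below CALB1 (-1.30).

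Glycolytic and hypoxia-responsive genes were lower as a group. Of 29 measured members, 25 were lower in the BCL11A siRNA group, with a list median of -0.22, and 4 fell: PKM, ENO2, SLC2A3 and PFKP, the platelet-type phosphofructokinase (-0.36, SE 0.05, adjusted p = 0.0104). Adjusted over the list alone, 13 fell and 0 rose. These add ENO1, an enolase (-0.25), HK2, a hexokinase (-0.40), LDHA, a lactate dehydrogenase (-0.23), and PDK1, the kinase that restrains pyruvate dehydrogenase (-0.52). ENO1, HK2, LDHA and PDK1 were named after their values were seen. The list passed the camera test (adjusted p = 7.33e-13), with adjusted p = 0.211 with an estimated correlation and 0.038 with fry. The calls over all genes rest on the brightest probe set of each gene. With the mean over probe sets 1 member fell over all genes and the list median was -0.14. PFKP then had -0.14 (limma adjusted p = 0.568), PKM -0.44 (0.581) and SLC2A3 -0.90 (0.0637). With no intensity trend 0 members fell over all genes, and with quantile normalization 6. Camera was passed in each of these fits. With the array sets as a block 12 members fell over all genes and 19 adjusted over the list alone, and camera gave 9.8e-19, with adjusted p = 0.00521 with an estimated correlation. The median was -0.17 within arrays 1 to 3 and -0.27 within arrays 4 to 6. It was -0.11 without control arrays 4, 5 and 6 and -0.37 without control arrays 1, 2 and 3, fits in which the sets are out of balance between the groups. Members of the list also differed between the array sets, by a median of 0.19 higher in arrays 4 to 6 (camera adjusted p = 1.34e-13). The centred mean of the list was 0.23 to 0.27 on control arrays 4 to 6, which stood apart, -0.03 to 0.07 on control arrays 1 to 3 and -0.35 to 0.001 on the BCL11A siRNA arrays.

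**Figure D4:**
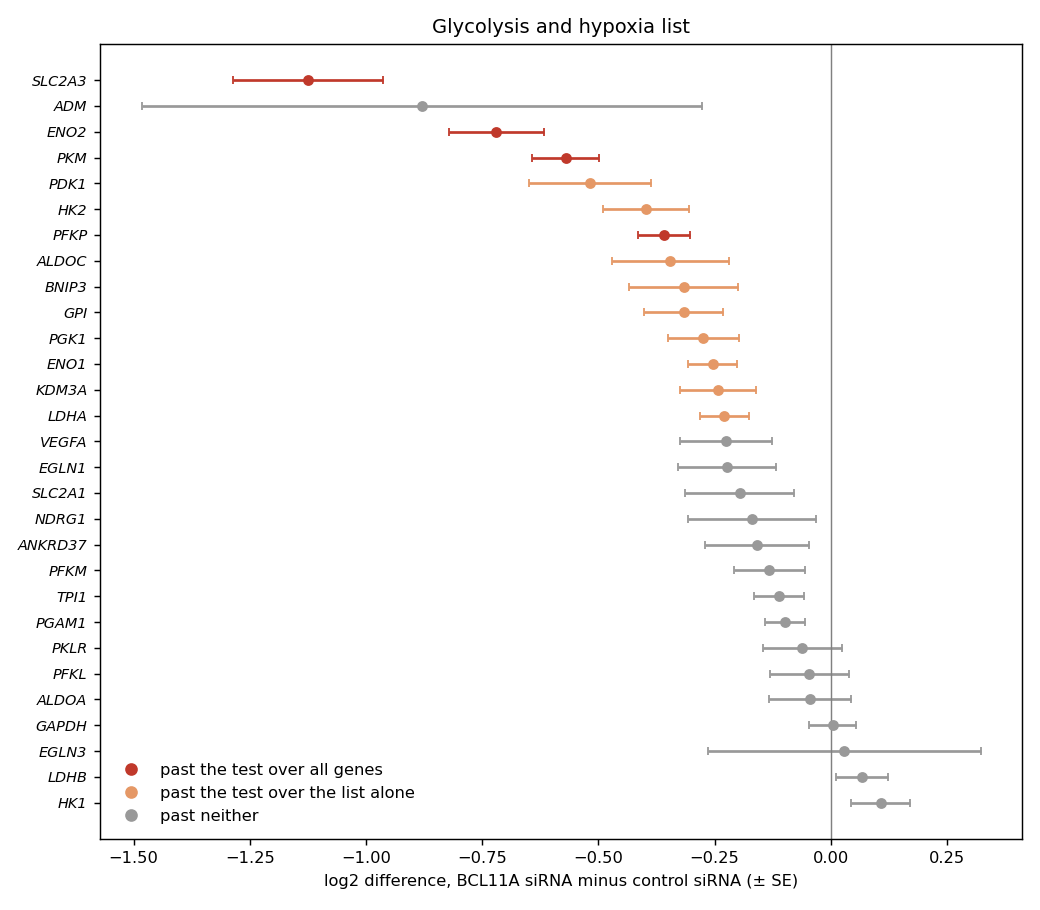
Log2 difference (x axis, BCL11A siRNA minus control siRNA, 6 arrays per group, bars ± SE) of the 29 measured genes of the glycolysis and hypoxia list. Red genes (4) passed the test over all genes, orange genes (9 more, 13 in all with red) passed adjusted over the list alone, and 25 genes lie below 0.

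Genes of terminal erythroid maturation were also lower as a group. Of 27 measured members, 25 were lower, with a median of -0.14. CA1 fell over all genes, and adjusted over the list alone 6 fell, among them BPGM, which makes the bisphosphoglycerate that tunes oxygen release (-0.46), TRIM58, a ubiquitin ligase of late erythroblasts (-0.28), and MXI1, an antagonist of MYC (-0.37). Camera gave an adjusted p of 1.9e-07, with adjusted p = 0.344 with an estimated correlation and 0.0963 with fry. With the array sets as a block 8 members fell (11 adjusted over the list alone), SLC4A1 among them (-0.43, adjusted p = 0.000556 against 0.517 without the block). Camera then gave 3.9e-12, with adjusted p = 0.0529 with an estimated correlation and 0.00043 with fry. List medians were -0.13 within arrays 1 to 3 and -0.17 within arrays 4 to 6, and the list was higher in arrays 4 to 6 than in arrays 1 to 3 by a median of 0.19. Control arrays 4 to 6 stood apart, the mean of the list, centred per gene, being 0.24 to 0.28 on them and -0.21 to 0.01 on the other 9 arrays.

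Heme synthesis, membrane and other erythroid lists did not pass over all 12 arrays at the deposited scaling and without the block. Of 21 genes of heme synthesis and iron handling 16 were lower (median -0.08, camera adjusted p = 0.112), CPOX, UROS, FLVCR1 and SLC40A1 having the smallest p (-0.23, -0.16, -0.17 and -0.08). That list passed with quantile normalization (adjusted p = 0.0209) and without control array 1, 2 or 3 or BCL11A siRNA array 5 (0.0432, 0.0192, 0.0326 and 0.0257). It also passed with the array sets as a block (adjusted p = 0.0254, and adjusted p = 0.258 with an estimated correlation). Fry with the block gave an adjusted p of 0.032 for this list and 0.032 for the red cell membrane and blood group list. Red cell membrane and blood group genes (13 of 20 lower, adjusted p = 0.448, or 0.0912 with the block) held ACKR1, the Duffy antigen (0.23), and SLC14A1, the Kidd antigen and urea transporter (-0.55), neither past the test. Neither list passed within arrays 1 to 3 (adjusted p = 0.818 and 0.84), and within arrays 4 to 6 both did, lower in the BCL11A siRNA group (0.00539 and 0.0258). Control arrays 4 to 6 had the highest centred list means of all 12 arrays, 0.10 to 0.16 for heme synthesis and 0.16 to 0.19 for the membrane list, against at most 0.05 and 0.10 on the others. The 3′ minus 5′ difference of ACTB also did not overlap between the groups within arrays 4 to 6. Both lists were higher in arrays 4 to 6 than in arrays 1 to 3, by medians of 0.12 and 0.18. Early erythroid progenitor genes (12 of 21 higher, 0.632) and erythroid transcription factors (20 of 28 lower, 0.339) did not pass. Adjusted over the list alone, the factors FOXO3 (-0.26) and STAT5B (-0.17) fell and LDB1 (0.19) rose, and FOXO3 passed over all genes with the block (adjusted p = 0.0349).

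The stress-response lists passed camera at the preset correlation, on opposite sides. Without the array sets as a block neither passed with an estimated correlation or with fry (adjusted p = 0.103 and 0.16). With the block both passed fry (adjusted p = 0.00147 and 0.045). Of 29 measured genes of the amino acid and endoplasmic reticulum stress response, 22 were lower (median -0.08); 0 passed over all genes and 4 fell adjusted over the list alone. These were DDIT3, the stress-induced factor CHOP (-0.42), TRIB3, a pseudokinase induced by it (-0.52), SESN2, a stress-induced restraint on growth signalling (-0.40), and VLDLR, a lipoprotein receptor (-0.51). Camera gave 0.00708, with adjusted p = 0.352 with an estimated correlation. With the block 4 members fell over all genes and 8 adjusted over the list alone (1 rose); the 4 were TRIB3, SESN2, DDIT3 and DDIT4, a restraint on growth signalling named after its value was seen (adjusted p = 0.00303, 0.0299, 0.0391 and 0.0124). Camera then gave 0.000775, with adjusted p = 0.0738 with an estimated correlation. Medians were -0.06 within arrays 1 to 3, where the list did not pass (adjusted p = 0.083), and -0.10 within arrays 4 to 6 (0.004), and the list was higher in arrays 4 to 6 by 0.15. Its centred mean was 0.11 to 0.17 on control arrays 4 to 6, which stood apart, and -0.18 to 0.004 on the other 9 arrays. Of 17 heat shock and chaperone genes 14 were higher (median 0.12) and 0 passed on their own, HSPB1 (0.22), HSPA9 (0.19), HSPE1 (0.22) and BAG3 (0.25) having the smallest p. Camera gave 2.42e-05, with adjusted p = 0.344 with an estimated correlation. With the block 1 member rose, the mitochondrial chaperonin HSPE1 (camera adjusted p = 1.4e-06, and adjusted p = 0.19 with an estimated correlation). Adjusted over the list alone, with the block, 7 rose and DNAJB4, named after its value was seen, fell. The median was 0.05 within arrays 1 to 3, where the list did not pass (adjusted p = 0.267), and 0.21 within arrays 4 to 6 (adjusted p = 3.7e-08), where the control arrays stood apart. The mean of the list, centred per gene, was -0.08, -0.16 and -0.16 on those 3 arrays and -0.01 to 0.13 on the other 9, with BCL11A siRNA arrays 4 to 6 overlapping BCL11A siRNA arrays 1 to 3.

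Inflammatory and mast cell lists passed camera at the preset correlation. Without the array sets as a block neither passed with an estimated correlation or with fry (adjusted p = 0.0963 and 0.0605). With the block both passed fry (adjusted p = 0.032 and 0.00043). Of 24 measured inflammatory genes 19 were lower (median -0.19), and only 6 of the 24 had a mean log2 value above 6. CXCL8, a neutrophil-attracting chemokine, fell (-1.89, SE 0.34, adjusted p = 0.0312) at a low level, a call kept only without control array 1, 2 or 3 when 1 array at a time was left out (lost in 9 of 12 fits, adjusted p up to 0.0969), and adjusted over the list alone SOD2, a mitochondrial superoxide dismutase, fell too (-0.29). Camera gave 0.01, with adjusted p = 0.344 with an estimated correlation, and 0.0101 with the array sets as a block, with adjusted p = 0.232 with an estimated correlation. It did not pass within arrays 1 to 3 (median -0.15, adjusted p = 0.535), and within arrays 4 to 6 it did (-0.32, adjusted p = 0.004). The centred mean of the list was 0.17 to 0.34 on control arrays 4 to 6, which stood apart, and -0.36 to 0.13 on the others. Of 21 mast cell, basophil and eosinophil markers 13 were higher (median 0.15). The lipoxygenase gene ALOX5 rose adjusted over the list alone (0.33), and the tryptases TPSB2 and TPSAB1 differed by 0.53 each (adjusted p = 0.282 and 0.296, or 0.00571 and 0.0142 with the block). Camera gave 0.0402, with adjusted p = 0.211 with an estimated correlation, and 0.00924 with the block, with adjusted p = 0.0606 with an estimated correlation. With the block these 2 members rose over all genes, and adjusted over the list alone 4 rose. The 2 added were ALOX5 and PRG2, the eosinophil major basic protein (0.17), which was named after its value was seen. The list passed within arrays 1 to 3 (median 0.05, adjusted p = 0.00746) but not within arrays 4 to 6 (0.08, adjusted p = 0.338), nor without _x_at and _s_at probe sets (adjusted p = 0.634), and 5 of 8 bright members were lower in arrays 4 to 6 in both groups.

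Lists of markers of other blood lineages did not pass over all 12 arrays, apart from the neutrophil and monocyte list under some alternatives. Neutrophil and monocyte markers were higher in 19 of 31 genes (camera adjusted p = 0.0714, or 0.0588 with the array sets as a block), and adjusted over the list alone 4 granule genes rose, AZU1 (0.51), LYZ (0.72), MPO (0.65) and ELANE (0.67), and CYBB, an oxidase subunit of phagocytes named after its value was seen, fell (-0.67). Of these AZU1 passed over all genes with the block (adjusted p = 0.0478). Only 2 of the 31 members had a mean log2 value above 6. The list passed without dim probe sets (camera adjusted p = 0.0195), with array weights (0.0434), and without control array 4, 5 or 6 or BCL11A siRNA array 5 (0.0167, 0.0481, 0.036 and 0.0341). Within arrays 1 to 3 this list passed (median 0.16, adjusted p = 0.0124), and within arrays 4 to 6 it did not (-0.003, adjusted p = 0.645). Megakaryocyte and platelet markers gave 15 of 24 lower (0.448), with ITGA2B past the test over all genes. B lymphoid markers gave 14 of 21 lower (0.505). For T and natural killer cell markers (12 of 23 lower, 0.756) the median (-0.03) had the opposite sign to the mean (0.06) and to the camera direction, and only CD247, a T cell receptor subunit at a low level here, passed (-1.09, adjusted p = 0.0417). Hematopoietic stem and progenitor markers gave 10 of 19 lower (0.708), with a median of -0.09 and a mean of 0.002. Endothelial and stromal markers gave 10 of 19 higher (0.448). With an estimated correlation adjusted p was at least 0.331 for each of these lists.

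The regulatory and signalling lists did not pass either. Reported repressors of fetal globin and partner complexes of BCL11A gave 19 of 34 higher (camera adjusted p = 0.448), and only CHD3, a nucleosome remodelling subunit, fell adjusted over the list alone (-0.34). Fetal-stage developmental genes gave 12 of 18 lower (0.22), and TFPI, an inhibitor of coagulation (-0.34), and PLAGL1, an imprinted zinc-finger gene (-0.26), fell adjusted over the list alone. Cell cycle and DNA replication genes gave 25 of 38 lower (0.325), with CCND2 (-0.21), BUB1 (-0.21), CDKN1B (-0.34) and TTK (-0.25) lower and CDC25A (0.20, named after its value was seen) higher adjusted over the list alone. Targets of p53 and apoptosis genes gave 17 of 27 lower (0.364), with 3 lower adjusted over the list alone, MDM2, the ubiquitin ligase of p53 (-0.38), SESN2 (-0.40) and MCL1, a survival factor (-0.16). Interferon response genes gave 24 of 38 lower (0.204), IFI27 having the smallest p (-0.64), and cytokine and STAT5 genes 21 of 36 lower (0.505), with ID2 at 0.17. In the interferon and cytokine lists 0 genes passed without the block, over all genes or adjusted over the list alone. None of these 6 lists passed camera with the block either (adjusted p of at least 0.0993). Fry with the block was passed by the interferon list (adjusted p = 0.0367). The block also brought single members past the test over all genes, all lower. These were TFPI and PLAGL1 (adjusted p = 0.0395 and 0.0474), BUB1 and CDKN1B (0.0449 and 0.0396), SESN2 and TP53INP1, a p53-induced protein named after its value was seen (0.0299 each), and IFI27 (0.00633). Adjusted over the list alone, the block gave 2 lower interferon genes, and 4 lower and 1 higher cytokine genes.

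**Figure D5:**
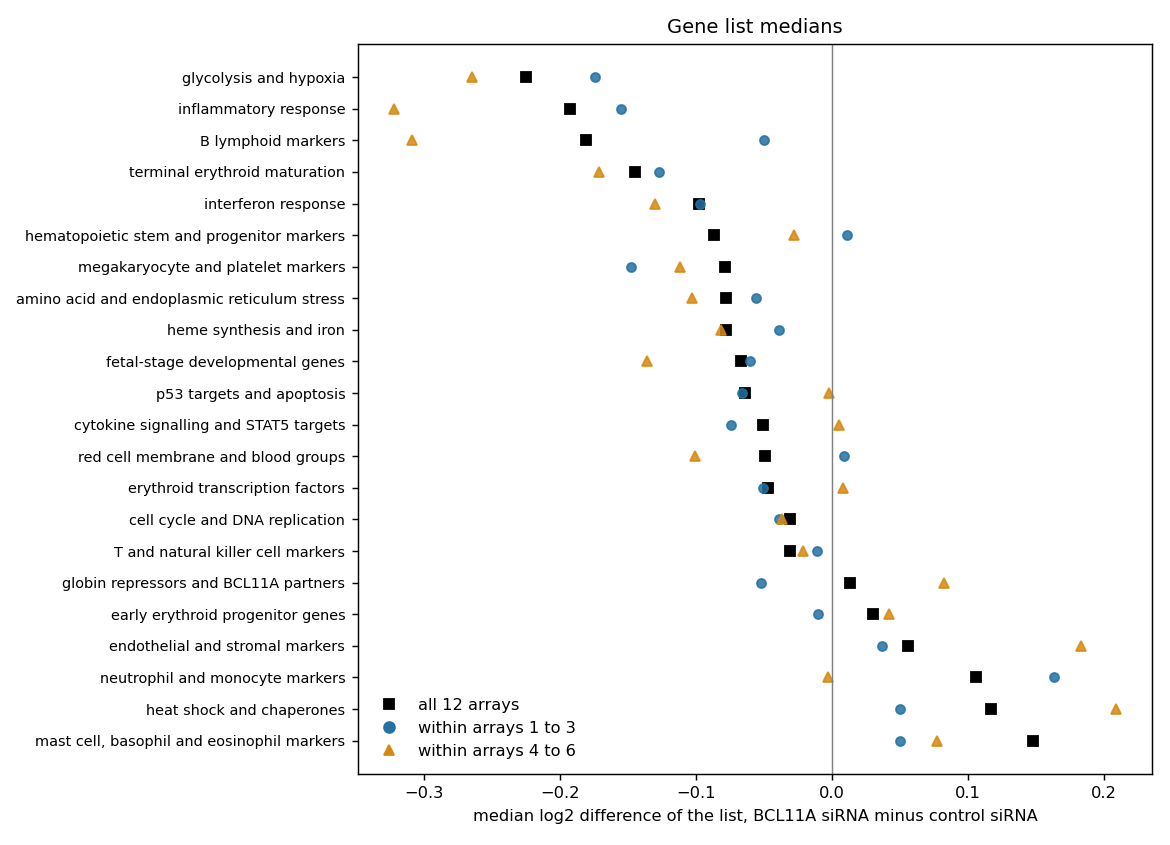
Median log2 difference (x axis, BCL11A siRNA minus control siRNA) of each of the 22 tested gene lists; squares are all 12 arrays, circles arrays 1 to 3 and triangles arrays 4 to 6, without error bars. The glycolysis and hypoxia list has the lowest median over all 12 arrays (-0.22) and stays below 0 in both sets.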

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

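The comparisons of arrays 1 to 3 with arrays 4 to 6 were chosen only after the result they bear on had been seen; the correlation of the BCL11A probe sets was chosen before its value was known.

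In 4 of 88 groups of 6 arrays, 1 array lay far from the other 5 by Dixon's criterion, where chance alone would give about 4.4. SCRN1 read 35.9 on BCL11A siRNA array 2 against 63.7 to 76.4 on the others of its group. SERPINE2 read 58.5 on the same array against 72.3 to 80. BCL11A probe set 219497_s_at read 559.6 on control array 4 against 384.5 to 427.7. The least bright HBB probe set, 1562981_at, read 230.4 on control array 5 against 264.4 to 286.6.

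The BCL11A probe sets overlapped between the groups while all 3 γ-globin probe sets separated them. Over all 12 arrays the difference of the brightest BCL11A probe set (log2 -0.21) was no smaller in size than theirs (0.18, 0.17 and 0.16). Without control array 4, its outlier, the BCL11A difference was -0.13. The γ-globin differences ran from 0.147 to 0.195 when any 1 array was left out. A swap of arrays between the groups was not tested, since the γ-globin values that would show it are part of the pattern. Probe sets that read something other than BCL11A may still contribute: pairwise correlations of the 4 probe sets over the 12 arrays, after removal of group means, ran from 0.102 to 0.873, which neither shows that they read 1 transcript nor that they do not. A knockdown that had partly worn off by day 7, or that acts on the protein more than on the transcript, could give the same values, and the arrays hold no test of either.

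Arrays 4 to 6 differed from arrays 1 to 3 in the same direction in both groups for part of the genes. Of 8636 genes with a mean log2 value above 6, 5.16% separated the sets on the same side in both groups, where chance gives 0.5%. The count of 377 genes rests on 1 term fitted over both groups, so a larger difference in 1 group can drive a call. Of 100 pairings of a split of the control arrays into 3 and 3 with such a split of the BCL11A siRNA arrays, only this one gave 377 genes, and the highest other gave 2. RNA quality cannot be told apart from the sets on 2 control transcripts: 0 of them (GAPDH and ACTB) had a 3′ minus 5′ difference that separated the sets on the same side in both groups, but mean GAPDH was lower in arrays 4 to 6 in both (0.50 to 0.42 and 0.50 to 0.39 with BCL11A siRNA). ACTB separated the sets on BCL11A siRNA arrays alone (0.66 to 0.91 on arrays 1 to 3, 0.53 to 0.64 on arrays 4 to 6). Scaling is argued against, since 504 genes differed between the sets after quantile normalization. Separate culture runs, donors or array batches may lie behind the sets, the labels name none of these, and no biological explanation was tested.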

How the results depend on the processing

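The array sets as a block, the fits within each set and the fits without 3 control arrays were chosen only after the data had been seen, and the rest were planned. All 17 named genes kept their direction in every alternative run that measured them. Where _x_at and _s_at probe sets were left out, 14 were measured, since 3 have no other probe set. For left-out arrays the kept direction follows from their groups not overlapping, where the probe set stays the same. Between 4 and 17 of the named genes stayed past the test. The number of arrays and the low signal of dim probe sets limit what can be called. Where no construction of a fit shows it, the cause was not tested.

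Against 36 genes (5 higher, 31 lower; 14% higher), median centring gave 22 (6 higher, 16 lower; 27.3% higher), quantile normalization 10 higher and 37 lower (21.3% higher), the fit without dim probe sets, which tests fewer genes, 88, the mean over probe sets 8, no intensity trend 4 (2 higher, 2 lower), and the robust variance model 56. An adjusted p under 0.01 left 12 and a 1.5-fold minimum left 17. With the array sets as a block there were 203, within arrays 1 to 3, with fewer arrays, 9, and within arrays 4 to 6 119. Without control arrays 4, 5 and 6 there were 18 (8 higher, 10 lower), and without control arrays 1, 2 and 3 1002 (558 higher, 444 lower); both leave the array sets out of balance between the groups. Leaving out each array in turn gave 19 to 42, with 21 without control array 4, 22 without control array 6, 19 without BCL11A siRNA array 2, and 21 without BCL11A siRNA array 3 or array 4. Against 31 probe sets the counts were 11 with low values raised to the 20th percentile, 56 without dim probe sets, 0 with no intensity trend, 51 with the robust model, 247 with the array sets as a block, 2 within arrays 1 to 3, 55 within arrays 4 to 6, 13 without control arrays 4, 5 and 6, and 1206 without control arrays 1, 2 and 3. Each array in turn gave 13 to 37: 17 without control array 4, 13 without control array 6, and 19, 14, 19 and 16 without BCL11A siRNA arrays 2, 3, 5 and 6.

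The array numbers were not taken to pair single arrays, although numbers 1 to 3 and 4 to 6 mark the same sets in both groups: deviations of same-numbered arrays correlated at 0.42, 0.139, 0.225, 0.218, 0.205 and 0.029, not all above 0.1, and not every array correlated best with its own number. With the replicate number as a block 161 genes and 168 probe sets were called, more than without it, and the heme synthesis and neutrophil lists passed (0.0362 each). This block also takes up the difference between arrays 1 to 3 and 4 to 6.

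The γ-globin probe sets passed the limma test with the robust model (0.175, 0.172 and 0.162, adjusted p 0.0351, 0.0422 and 0.0498) and, for 213515_x_at and 204419_x_at (0.175 and 0.172), without dim probe sets (0.0387 and 0.0462). Over all alternatives the adjusted p of 213515_x_at ran up to 0.712, within arrays 1 to 3. The BCL11A, globin and named list values below changed sign, and where they did the limma adjusted p was at least 0.499. BCL11A 219498_s_at gave 0.0138 with median centring, 0.0178 within arrays 1 to 3 and -0.0584 to 0.00711 leaving out each array, and 210347_s_at 0.00982 with quantile normalization, 0.00829 with median centring, 0.00756 within arrays 1 to 3 and -0.0828 to 0.0237. Within arrays 1 to 3 the α-globin probe sets gave -0.0413, -0.0377, -0.0498, -0.0462, -0.051 and -0.0848, and HBB -0.069, -0.109 and -0.126. With quantile normalization 211745_x_at gave -0.0056 and 214414_x_at -0.0158. HBB 1562981_at gave 0.0167 with quantile normalization, 0.0383 with median centring, 0.000465 with array weights, 0.0429 within arrays 1 to 3 and -0.0484 to 0.0563 leaving out each array. HBQ1 gave 0.0147 with median centring, 0.136 within arrays 4 to 6 and -0.0673 to 0.0251, HBM -0.000279 to 0.164, and HBE1 217683_at, -0.352 over all arrays, 0.169 within arrays 4 to 6. FLVCR1 gave 0.0583 with the mean over probe sets and HSPA9 -0.0166 without _x_at and _s_at probe sets.

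For gene lists the values are adjusted p. Of the 6 lists past camera, 3 were left without _x_at and _s_at probe sets, 0 with an estimated correlation and 1 with fry. With an estimated correlation they had 0.211 (glycolysis), 0.344 (terminal maturation), 0.352 (endoplasmic reticulum stress), 0.344 (heat shock), 0.344 (inflammatory) and 0.211 (mast cell), and with fry all but glycolysis were lost (0.0963, 0.103, 0.16, 0.0963 and 0.0605). With the array sets as a block fry was passed by 9 lists: these 6, heme synthesis, red cell membrane and interferon. Without _x_at and _s_at probe sets heat shock had 0.705, inflammatory 0.208 and mast cell 0.634. Within arrays 1 to 3 endoplasmic reticulum stress had 0.083, heat shock 0.267 and inflammatory 0.535, and within arrays 4 to 6 mast cell had 0.338. The mast cell list also had 0.0617 with median centring, 0.0861 with the mean over probe sets and 0.0542 with no trend. Leaving out each array gave it 0.0208 to 0.099, with 0.0527 without control array 4 and 0.099, 0.0601, 0.0778 and 0.0554 without BCL11A siRNA arrays 1, 2, 3 and 6, and gave endoplasmic reticulum stress 0.00125 to 0.0601, the last without BCL11A siRNA array 2.

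Lists with adjusted p over 0.05 over all arrays changed direction as follows, none of them past the test where they did. Early progenitor genes had 0.964 with quantile normalization and 0.486 within arrays 1 to 3, and globin repressors 0.365 within arrays 1 to 3. Stem cell markers had 0.794 without _x_at and _s_at probe sets, 0.421 within arrays 1 to 3 and 0.594 to 0.975 leaving out each array. B lymphoid markers had 0.692 without dim probe sets, 0.989 with the mean over probe sets, 0.687 without _x_at and _s_at probe sets and 0.807 within arrays 1 to 3. T and natural killer cell markers had 0.884 with median centring, 0.96 with low values raised, 0.362 without dim probe sets, 0.727 within arrays 4 to 6, 0.529 with fry and 0.596 to 0.98 leaving out each array. Red cell membrane genes had 0.147 to 0.999 leaving out each array, with 0.999 without control array 4, where the direction changed, and passed within arrays 4 to 6 (0.0258).

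The heme synthesis and iron list passed with quantile normalization (0.0209), with the array sets as a block (0.0254) and within arrays 4 to 6 (0.00539), and had 0.0192 to 0.389 leaving out each array. The neutrophil and monocyte list passed without dim probe sets (0.0195), with array weights (0.0434) and within arrays 1 to 3 (0.0124), and had 0.0167 to 0.177 leaving out each array.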

Other observations

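The gene lists tested here in addition to those fixed in advance, and the splits that keep the array sets balanced, were chosen after the first results had been seen but before their own results were known, while the tests of scaling and of array sets on the glycolysis list, the genes that differ with the array sets as a block and the genes whose response differs between the sets were chosen only after the result had been seen.

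With the array sets as a block, 167 genes passed beyond the 36, and those given here were picked after their values were seen. Among genes that fell were TUBA1A, an α-tubulin (log2 -0.56, limma adjusted p = 4.39e-05), SAT1, which breaks down polyamines (-0.52, adjusted p = 0.000341), TXNIP, the thioredoxin inhibitor (-0.48, adjusted p = 0.000323), and AQP3, a water and glycerol channel (-0.38, adjusted p = 0.00118). Genes of the glucose and low-oxygen response in this group included BNIP3 (-0.32), PFKFB4 (-0.30) and FAM162A (-0.32), with adjusted p of 0.00397, 0.00862 and 0.00318. These are examples, and the group held more such genes, PGK1 and LDHA among them. Among genes that rose were ESPN, an actin-bundling protein (0.74, adjusted p = 0.003), RHEX, a regulator of erythroid expansion (0.33, adjusted p = 0.0103), SRM, the spermidine synthase (0.34, adjusted p = 0.0197), and NUP93, a nuclear pore subunit (0.29, adjusted p = 0.0287). Without the block none of these passed, the adjusted p running from 0.0537 for FAM162A to 0.337 for BNIP3.

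Lists of basic cell machinery passed camera as higher in the BCL11A siRNA group over all 12 arrays and within arrays 4 to 6 but not within arrays 1 to 3, and whether the sets differ in this was not tested. Of 79 genes of mitochondrial oxidative phosphorylation 64 were higher (median 0.08, camera adjusted p = 4.18e-08), as were 30 of 34 proteasome subunits (0.09, 2.62e-07), 50 of 59 cytosolic ribosomal proteins (0.02, 0.00168), and 16 of 16 genes of the chaperonin TRiC and ribosome biogenesis (0.08, 5.41e-06). With an estimated correlation these lists had adjusted p = 0.373, 0.373, 0.523 and 0.353, and with fry 0.235 each, and 0 of their genes passed over all genes, with or without the array sets as a block. Within arrays 1 to 3 their medians were -0.02, -0.02, -0.01 and 0.01 (camera adjusted p = 0.961, 0.961, 0.961 and 0.317), and within arrays 4 to 6 0.15, 0.19, 0.07 and 0.17 (1.01e-12, 1.35e-12, 9.57e-06 and 9.48e-08). Control arrays 4 to 6 stood apart on 2 of these lists. List means, centred per gene, were -0.17 to -0.13 for TRiC and ribosome biogenesis against 0.02 to 0.10 on the other 9 arrays. For the proteasome they were -0.19 to -0.06 against -0.02 to 0.13. For oxidative phosphorylation and ribosomal proteins BCL11A siRNA array 2 (-0.062 and -0.048) lay within the range of control arrays 4 to 6 (-0.162 to -0.021 and -0.056 to -0.031). Cholesterol synthesis (12 of 17 lower, camera adjusted p = 0.0617), histone genes (33 of 58 lower, 0.796), HOXA and HOXB genes (6 of 11 higher with a median of 0.10, against a camera direction of lower, 0.884) and aminoacyl-tRNA synthetases (8 of 15 higher, 0.306) did not pass. With the block cholesterol synthesis passed (camera adjusted p = 0.0401, but 0.122 with an estimated correlation), and within arrays 4 to 6 the synthetases did (0.0112).

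The response to BCL11A siRNA differed between the array sets for 8 genes by the interaction term of limma. G0S2, an inhibitor of fat breakdown, was 0.48 higher within arrays 1 to 3 and lower by -0.29 within arrays 4 to 6 (adjusted p = 0.0074). MLC1, a membrane protein of glia, gave -0.09 and 0.50 (adjusted p = 0.0074), and PNMT, the enzyme that makes adrenaline, gave 0.26 and 0.88 (adjusted p = 0.0291). The others were PPP1R14B, NME1, ARHGDIA, FABP5 and LRRC43, with adjusted p of 0.0291 to 0.0432 and a difference higher within arrays 4 to 6 for each. For the 7 genes other than G0S2, control arrays 4 to 6 all lay below control arrays 1 to 3. On the main principal component (28.6% of the variance) control arrays 4 to 6 lay at 12.4 to 17.0 and the other 9 arrays at -8.19 to -2.12.

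For the lower glycolysis and hypoxia list, scaling between arrays is argued against, because the list median minus the median of all genes was -0.233 under quantile normalization. Each array set holds 3 arrays of each group, so an equal shift between the sets cancels and could not lower the list. The list was lower within both sets, with a median of -0.174 in the set where it was nearer 0. The size of the difference depends on which control arrays are used. It was -0.111 without control arrays 4, 5 and 6 (1 gene past the test) and -0.369 without control arrays 1, 2 and 3 (16 genes). Those fits also put the sets out of balance. A list of 29 hypoxia-inducible genes, none of them in the fixed list, was lower in 24 (median -0.18, camera p = 8.01e-06, adjusted p = 0.238 with an estimated correlation and 0.0331 with fry), which is consistent with a lower level of hypoxia-inducible transcripts beyond the fixed list, as a hypothesis (medians of -0.22 within arrays 1 to 3 and -0.21 within arrays 4 to 6, adjusted p = 0.0307 with the block and an estimated correlation). Whether it could follow from the siRNA or from cell density or oxygen in the cultures is open, since no array separates them.

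Other splits of the 12 arrays into 6 and 6 show how far a random grouping of these arrays reaches. Of 100 splits, drawn from 462 and with the real one included, only the real one gave as many as 36 genes or 31 probe sets. The highest other counts were 2 genes and 1 probe set. A further 100, the real one again included, were drawn from the 200 splits that place 3 arrays of each array set in each group. Only the real one gave as many genes, probe sets or genes with the sets as a block (highest other 1 for each). A random grouping of these arrays is thus argued against as the source of these counts. The splits measure only the spread between arrays, which may be technical, so they cannot exclude a chance difference between cultures. The split of arrays 1 to 3 against arrays 4 to 6 was not among the first 100 drawn. Run separately, it gave 71 genes, more than the 36, which points to a structure of the samples. With the sets as a block the groups differ in 203 genes. For the 6 lists past the camera test chance cannot be excluded, since 19 of 100 splits gave as many (highest other 11), although 2 of 100 did so among the splits with balanced sets (highest other 6), a share under 0.05. For the glycolysis and hypoxia list 2 of 100 splits gave a camera p as low as 3.33e-14, counting the real one (the other gave 1.51e-14). With balanced sets 1 of 100 did (lowest other 3.05e-11). These shares lie under 0.05, but the list had the smallest camera p of the 22 lists in the real split. Other splits were not compared on their own smallest p over the lists, so the shares do not exclude chance.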
